A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

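Per the labels, total RNA of 8 coleoptiles per sample was hybridised to 12 Agilent rice expression arrays, with 400 ng of control RNA labelled with Cy3 and 400 ng of UV-B RNA labelled with Cy5. Per the file headers, the arrays were read with Agilent Feature Extraction 11.5.1.1, and the authors deposited its output for each array: spot and background intensity per channel, flags, signals after dye normalization by LOWESS, and log10 ratios of Cy5 over Cy3. The authors' deposited series table holds log2 ratios that equal those of the processed signals within 5e-10, so its scale and direction are known, and its column medians were -0.09 to 0.01. No rice spot was saturated on any array.

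Each array carried 45151 spots, of which 1417 were controls and 42124 held 41908 probes of 60 bases for 29690 rice loci. Of these loci 7801 had more than 1 probe. Loci and descriptions came from the array files. None of the loci tested matched the reference gene table (0 of 24162), so symbols and genome positions are not given. Samples were grouped by the treatment labels of both channels. Per the series design the 3 sets came from different occasions, so replicate numbers pair the samples. The deviations of the 20 and 60 min ratios from their means correlated at 0.46, 0.12 and 0.42 within occasions and at -0.43 to 0.09 between occasions. Each occasion lay on its own slide, each comparison always at the same position, and all arrays were scanned on 1 day, so slide and occasion cannot be told apart.

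Mean intensities were corrected for local background by normexp with an offset of 50 on all spots. They were normalized within each array by loess (span 0.3) with limma 3.58.1 in R 4.3.3. Only spots of rice loci without an outlier flag had weight in loess, and spots with such a flag were left out. Probes well above background in Cy3 or Cy5 on at least 6 of 12 arrays were kept, and each gene was represented by its probe of highest mean intensity, giving 24162 genes. Among 2735 genes with more than 1 probe and a call at 60 min, called probes differed in sign for 35. The arrays of a treated sample against control 1 and control 2, which correlated at 0.68 to 0.90 across genes, were averaged. This gave 6 ratios, 3 per time.

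The ratios of both times were fitted together by lmFit with time as the factor, moderated by eBayes and adjusted by Benjamini-Hochberg over all genes, with calls at an adjusted p under 0.05. The contrasts were 20 min against 0, 60 min against 0 and 60 minus 20 min. The main fit did not pair the times by occasion, and the replicate block did so as an alternative. Against 0 this block leaves the spread between occasions out of the test, so its counts there can be too high. For 60 minus 20 min the SD shown is that of differences paired by occasion, so it is not the spread behind p. Control 2 was set against control 1 per occasion, through the ratios of the same treated samples. The 30 gene lists were patterns matched to descriptions, and the 28 with at least 5 genes were tested by camera with a preset correlation of 0.01, adjusted over 84 tests. With an estimated correlation 0 of the 18 calls held. The p value of camera rose even where the estimated correlation was below the preset one. For the ubiquitin ligase list at 60 minus 20 min this correlation was -0.03, and unadjusted p went from 0.00084 to 0.027. A lost call thus does not by itself show that the genes of a list are correlated. Among lists with a lost call, however, the estimate was below the preset one only for the ubiquitin ligase and MAP kinase lists. It was 0.48 for ribosomal protein, 0.50 for histone and 0.48 for proteasome genes. For photosynthesis, WRKY and jasmonate genes it was 0.17, 0.14 and 0.12. Correlated genes stay open as a reason for the loss in the lists above the preset value. The effect of shared controls was simulated 50 times with unchanged samples. No fold was given for the named gene whose control was not well above background on any array. The bound from per-channel values after loess and quantile scaling of mean intensity, which are open to dye bias, equalled its fitted fold.

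Tests, gene lists and the rule for named genes were fixed before the data were examined. Called genes with the same sign on all 6 arrays of a time and a description other than hypothetical or uncharacterized were ranked. The 12 largest rises and 8 largest falls were named at each time, and 8 in each direction for 60 minus 20 min. Up to 3 called members were named per list. The test was checked on simulated data with 24162 genes. At 60 min it recovered 32 of 50 genes at the smallest simulated change, 46 of 50 changed 1.5-fold, 46 of 50 changed 2-fold and 50 of 50 changed 4-fold, and called 9 of 23962 unchanged genes. For 60 minus 20 min it recovered 4, 41, 45 and 50 of 50 and called 9 of 23962. At 20 min, where no change was simulated, it called 0 genes. The simulated ratios were independent and normal, without shared controls, effects of occasion or dye, or correlated genes. These counts thus do not show the rate of false calls in the real data. Alternatives covered background correction, scaling, probe filters, outlier flags, the variance model, blocks, single controls, all probes of a gene, a 2-fold threshold, single-time fits and leaving out each occasion. Figures were drawn with matplotlib 3.10.9.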

Results

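Transcript levels were measured in coleoptiles of the japonica rice cultivar Nipponbare, the sheaths that enclose the first leaves of a grass seedling. Seedlings grew for 3 days in red light at 25 °C until the coleoptiles were 3 to 4 mm long. They received UV-B from both sides for 10 min at 0.065 µmol m-2 s-1, a fluence of 39.0 µmol m-2. Coleoptiles were taken 20 and 60 min after UV-B began, and untreated controls just before (control 1) and just after (control 2) the irradiation. No untreated coleoptiles were taken at 20 or 60 min, so elapsed time and UV-B cannot be told apart. Each sample pooled 8 coleoptiles, and the set was repeated on 3 occasions, which are the biological replicates. On each occasion both treated samples were hybridised against both controls on 2-colour arrays, giving 12 arrays on 3 slides, with control RNA in Cy3 and UV-B RNA in Cy5 on all of them. Each array held 42124 spots for 29690 rice loci. Spots well above background made up 71.0% to 82.3% in Cy3 and 76.9% to 85.8% in Cy5, and the number of arrays limits the precision. Genes are named by locus and by the description given on the array, which can be old, and 24162 were tested. Ratios are log2 of UV-B over control, as mean ± SD over 3 occasions (n = 3).

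The first comparison asked which transcripts had changed 20 min after the onset of UV-B. Among called genes with a usable description, the largest rises belonged to 3 genes for early light-inducible proteins. These are chlorophyll-binding proteins of the thylakoid linked to protection from excess light. Os01g0246400 rose by 3.13 ± 0.34 (SD, n = 3), a fold of 8.73, Os07g0178800 by 2.94 ± 0.25 and Os07g0178700 by 2.32 ± 0.37. Os07g0178700 and Os07g0178800 are neighbours in locus order with the same description. Cross-hybridization, in which a probe also binds the transcript of a similar gene, stays open for them at both times. The regulators OsNAC3 (Os07g0225300, 2.04 ± 0.68), a NAM / CUC2-like gene (Os04g0515900, 1.79 ± 0.57) and MYB1 (Os02g0624300, 1.65 ± 0.33) rose, as did an EF-hand calcium-binding protein gene (Os09g0412300, 1.86 ± 0.84). Kinase genes Os01g0699500 (2.19 ± 0.93), Os02g0807900 (1.71 ± 0.52) and Os06g0241100 (1.47 ± 0.35) also rose. A DUF179 family gene (Os10g0330400, 1.56 ± 0.09) and a RING domain gene (Os02g0559800, 1.42 ± 0.59, control above background on 4 of 6 arrays) completed the 12 named rises. With the processed signals the ratios of Os02g0624300, Os02g0559800 and Os04g0515900 were 2.71, 2.74 and 2.53, but Os02g0624300 and Os02g0559800 were not called there. Os01g0699500, Os09g0412300 and Os02g0807900 were also not called with the processed signals. Falls were smaller. Heat shock factor RHSF2 (Os08g0546800) fell by 0.75 ± 0.13 on the log2 scale, and CBL-interacting protein kinase 2 (Os01g0206700) fell by 0.74 ± 0.23. Auxin-induced or SAUR genes Os09g0546300, Os09g0546100 and Os09g0547100 had ratios of -0.68 ± 0.37, -0.62 ± 0.07 and -0.59 ± 0.11. A DUF868 gene (Os01g0909400, -0.64 ± 0.33), a NUDIX hydrolase gene (Os02g0734300, -0.63 ± 0.08) and a CONSTANS-type zinc finger gene (Os04g0540200, -0.58 ± 0.04) were the other named falls. The falls of Os09g0546300 and Os01g0909400 were not called with the processed signals. The limma test called 978 genes at an adjusted p under 0.05, of which 655 rose and 323 fell, and 50 rises and 0 falls reached 2-fold. Adjusted p was 0.000118 for Os07g0178800 and 0.0471 for Os09g0412300. The share that rose was 67.0%, but 55.9% of 13359 genes under median centring. The count was 2321 with the occasion as a block, which leaves the spread between occasions out of the test against 0. It was 242 from the scanner software's processed signals, 40, 18 and 239 without occasion 1, 2 or 3, and 387 without the 60 min array of occasion 2 against control 2, which had the fewest spots above background. Of the 20 named genes only the 3 for early light-inducible proteins passed without each occasion in turn, and with no dye swap a probe's dye effect cannot be told apart from UV-B here.

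Over all tested genes 4.0% were called at 20 min. Among the gene lists at 20 min, 15 of 137 MYB genes rose and 3 fell (19 and 3 adjusted over the list alone), among them MYB1 and the R2R3 gene Os06g0205100 (0.94 ± 0.12, adjusted p = 0.00772). The MYB list did not pass the set test (adjusted p = 0.103). Of 58 WRKY genes, a family of plant defence regulators, 6 rose and 1 fell (19 and 3 adjusted over the list alone). The largest were Os01g0821600 (0.80 ± 0.19, control above background on 2 of 6 arrays), Os03g0321700 (0.59 ± 0.22) and Os05g0183100 (0.58 ± 0.21). The ratio of Os01g0821600 was 0.28 under median centring and 2.16 with the processed signals, so its size is uncertain. The WRKY list passed the set test upward (adjusted p = 0.0253, adjusted p = 0.906 with an estimated correlation). It turned downward under median centring without passing (adjusted p = 0.507). Of 31 AP2/ERF genes 4 rose and 0 fell (9 and 1 adjusted over the list alone). They included Os01g0141000 (1.26 ± 0.56), Os01g0693400 (0.52 ± 0.25) and Os04g0529100 (0.31 ± 0.06), the last with the opposite sign under median centring. The AP2/ERF set test gave adjusted p = 0.0614, and adjusted p = 0.0189 with the processed signals. Its pattern missed related genes by their descriptions. Counted after their values were seen, 13 ethylene responsive element binding factors outside it held 4 rises and 0 falls, and 1 and 0 with the processed signals. The pathogenesis-related list, with 5 rises and 2 falls among 124 genes (6 and 3 adjusted over the list alone), held 31 ERF domain factors with 4 of these rises and 0 falls, among them Os09g0309700 (0.46 ± 0.10) and Os08g0408500 (0.45 ± 0.12). These 31 held 2 rises and 0 falls with the processed signals, and 10 and 7 under median centring, where their median was -0.01 and not 0.07. In the NAC list 1 of 45 genes rose (1 adjusted over the list alone), Os05g0194500 (0.41 ± 0.18), and the list's pattern did not match OsNAC3 or Os04g0515900. Photolyases, which repair UV lesions in DNA with the energy of light, supplied the 3 rises among 25 DNA repair genes (8 rises and 2 falls adjusted over the list alone). Os06g0661800 rose by 0.74 ± 0.01, the 6-4 photolyase gene Os02g0204400 by 0.39 ± 0.15 and the CPD photolyase gene Os10g0167600 by 0.29 ± 0.03. The calls of Os02g0204400 and Os10g0167600 were lost with the processed signals and whichever occasion was left out, and under median centring the ratio of Os02g0204400 was 0.12 and not called. In the light signalling list 2 of 42 genes rose and 1 fell (4 and 6 adjusted over the list alone). The NPH3 gene Os11g0118300 (0.91 ± 0.05) and the HY5 gene Os01g0174000 (0.43 ± 0.03), a bZIP regulator of light responses, rose. The NPH3 gene Os04g0477000 fell by 0.28 ± 0.09, and the list's median was below 0 and its mean above. Of 100 auxin genes 2 rose and 8 fell (7 and 11 adjusted over the list alone), and of 355 redox genes 8 rose and 2 fell (6 and 2 adjusted over the list alone). Of the 55 genes named through a list at 20 min, 0 passed without each occasion in turn, and 38 were not called with the processed signals.

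Small shifts over many members were also measured at 20 min. Ribosomal protein genes had a median of 0.10, with 2 of 299 rising and 0 falling and 0 adjusted over the list alone (set test adjusted p = 1.69e-05, adjusted p = 0.906 with an estimated correlation). Histone genes had a median of 0.09, with 2 of 46 rising and 0 falling (6 and 0 adjusted over the list alone, set test adjusted p = 0.00494, adjusted p = 0.906 with an estimated correlation). Photosynthesis genes had a median of 0.14, with 3 of 92 rising and 1 falling (3 and 1 adjusted over the list alone). Their set test gave adjusted p = 0.00243, and adjusted p = 0.906 with an estimated correlation. The gene for the 22 kDa protein of photosystem II (Os04g0690800), which acts in the heat dissipation of excess light, rose by 0.62 ± 0.21. The MAP kinase list had a median of -0.03, with 0 of 32 genes rising and 1 falling (1 and 4 adjusted over the list alone). Its downward set test gave adjusted p = 0.0460, and adjusted p = 0.673 with an estimated correlation. That call was lost with the occasion as a block (adjusted p = 0.0798) and with the processed signals (adjusted p = 0.0761), and the list turned upward under median centring (adjusted p = 0.313). Median centring shifts each array by its median only, so dye differences that vary with intensity stay in its ratios. It gave further calls at 20 min, upward for the AP2/ERF (adjusted p = 0.0310), proteasome (adjusted p = 2.79e-07), tetrapyrrole (adjusted p = 0.0310) and cytoskeleton (adjusted p = 0.0186) lists and downward for seed storage (adjusted p = 0.0186).

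At 60 min the ratios of the early light-inducible genes were higher still, and genes of phenylpropanoid synthesis were among the largest rises. Os07g0178700 rose by 4.90 ± 0.13 (SD, n = 3), a fold of 29.9, Os01g0246400 by 4.75 ± 0.13 and Os07g0178800 by 4.73 ± 0.15. Chalcone synthase (Os07g0526400), the first enzyme of flavonoid synthesis, rose by 4.40 ± 0.70, a fold of 21.1, with the control above background on 4 of 6 arrays. A gene for phenylalanine ammonia-lyase (Os04g0518400), which opens the phenylpropanoid pathway, rose by 3.88 ± 0.07, a fold of 14.7. An isopenicillin N synthase family gene (Os04g0522500, 4.09 ± 0.23), a thioesterase gene (Os01g0882100, 3.58 ± 0.05) and a gene of the CREB family of bZIP regulators (Os06g0601500, 3.07 ± 0.07) rose. Kinase genes Os02g0807900 (3.52 ± 0.43) and Os06g0241100 (3.39 ± 0.13) rose as well. A bHLH gene (Os04g0301500, 4.49 ± 1.87) and a ZIM domain gene (Os03g0180900, 3.13 ± 1.33) rose with a wide spread. The control was above background on 4 of 6 arrays for Os04g0301500, and on 5 of 6 for Os04g0522500, Os02g0807900 and Os06g0241100. With the processed signals the ratio of chalcone synthase was 6.04, and those of Os04g0301500, Os04g0522500, Os02g0807900 and Os06g0241100 were 5.88, 5.60, 4.13 and 4.11. Neither Os04g0301500 nor Os03g0180900 passed without occasion 1 (3.94 and 2.80) or occasion 2 (3.95 and 2.70), and without occasion 3 the ratios were 5.57 and 3.90, while the other 18 named genes passed without each occasion in turn. The largest named fall in the main fit was that of CBL-interacting protein kinase 2 (Os01g0206700, -1.74 ± 0.17). Phytochrome-interacting factor 3 (Os12g0610200), a bHLH protein that binds light-activated phytochrome, fell by 1.38 ± 0.15 on the log2 scale. A START domain gene (Os11g0245500) had a ratio of -1.37 ± 0.25, the DUF868 gene Os01g0909400 of -1.35 ± 0.19 and a further bHLH gene (Os03g0725800) of -1.32 ± 0.18. Auxin-induced and SAUR genes Os02g0445100 (-1.33 ± 0.16), Os09g0546100 (-1.28 ± 0.09, but -2.40 with the processed signals) and Os09g0546000 (-1.28 ± 0.03) fell. The limma test called 7042 genes, of which 4078 rose and 2964 fell, and 460 rises and 43 falls reached 2-fold. The share that rose was 57.9%, but 41.2% from the processed signals, and the count was 15768 under median centring and 3182, 3753 and 3595 without occasion 1, 2 or 3. With no dye swap, dye effects of probes limit these calls as they do at 20 min.

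**Figure D1:**
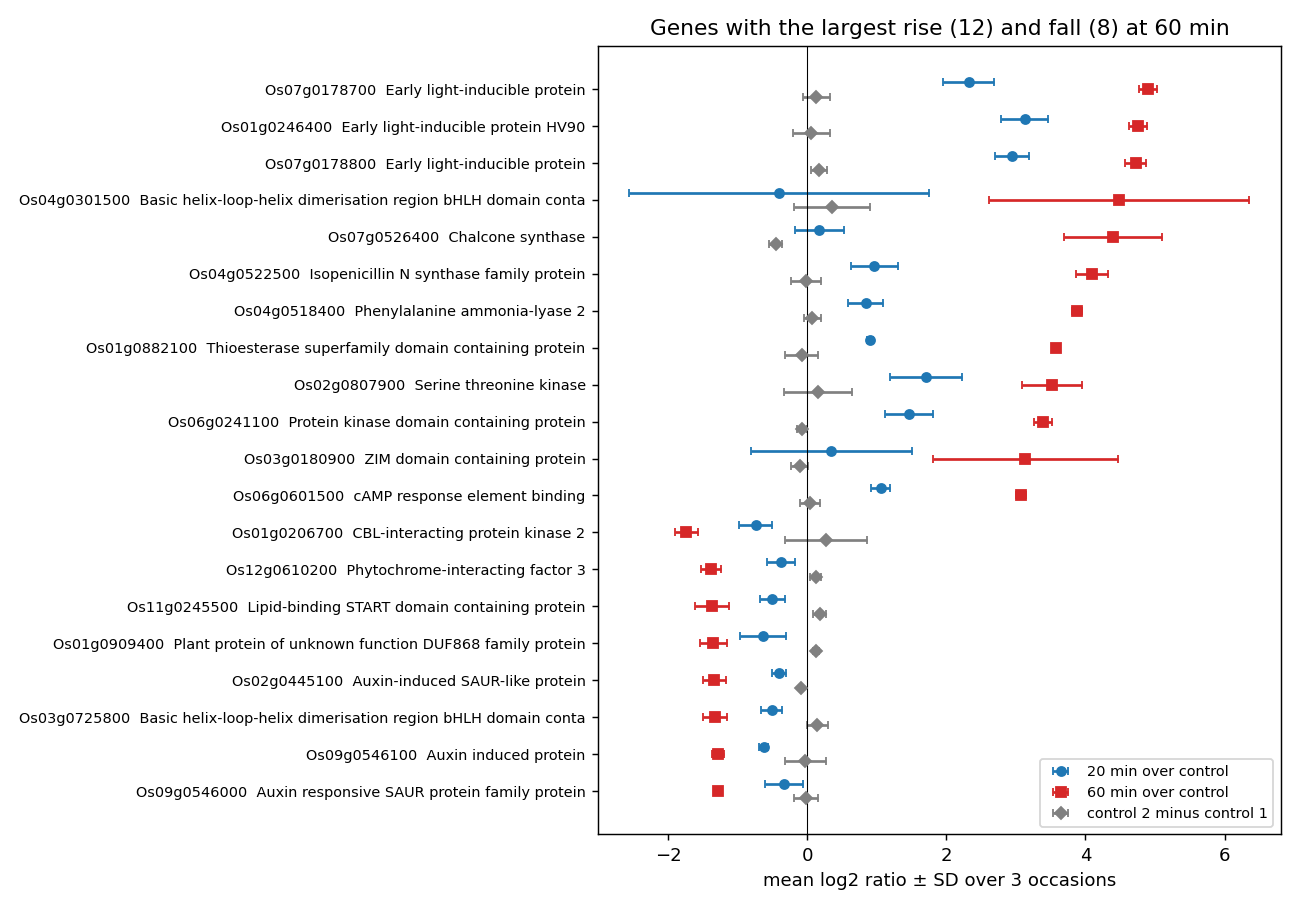
Mean log2 ratio and SD over 3 occasions (horizontal axis) for the 12 genes with the largest rise and the 8 with the largest fall at 60 min, at 20 min (blue circles), at 60 min (red squares) and for control 2 minus control 1 (grey diamonds). Os07g0178700 lies at 2.32 at 20 min and 4.90 at 60 min, and chalcone synthase (Os07g0526400) at 0.17 and 4.40.

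Phenylpropanoid and flavonoid genes rose at 60 min in 27 of 64 cases, 7 fell and 30 did not pass (30 and 8 adjusted over the list alone). Beside chalcone synthase and Os04g0518400, the phenylalanine ammonia-lyase gene Os05g0427400 rose by 2.88 ± 0.69. The list passed the set test (adjusted p = 0.00343, adjusted p = 0.816 with an estimated correlation). Jasmonate genes had a median of 0.55, with 19 of 35 rising and 2 falling (21 and 2 adjusted over the list alone). One of the 19 was a potassium channel gene (Os07g0108800, 0.29 ± 0.09) that the pattern matched only by its letters. The largest called in the list were ZIM domain genes Os03g0180900, Os03g0181100 (1.90, adjusted p = 0.0395, with a wide spread, and 2.62 without occasion 3) and Os10g0392400 (1.89 ± 0.54), a family that includes repressors of the jasmonate response. The pattern missed 6 oxo-phytodienoic acid reductase genes, a family with enzymes of jasmonate synthesis, of which 5 rose and 0 fell. Chosen after its values were seen, Os06g0216300 rose by 1.98 ± 0.37. The set test gave adjusted p = 1.69e-05, and adjusted p = 0.673 with an estimated correlation. WRKY genes rose in 24 of 58 cases and fell in 5 (30 and 6 adjusted over the list alone). Among them were Os01g0821600 (2.38 ± 0.16, control above background on 4 of 6 arrays, 3.89 with the processed signals), WRKY transcription factor 45 (Os05g0322900, 1.89 ± 0.18) and WRKY transcription factor 10 (Os05g0537100, 1.74 ± 0.68). The WRKY set test gave adjusted p = 0.00696, adjusted p = 0.906 with an estimated correlation, and adjusted p = 0.945 under median centring. In the abscisic acid and dehydration list 28 of 90 genes rose and 10 fell (35 and 10 adjusted over the list alone). A late embryogenesis abundant 3 family gene (Os01g0314800, 2.15 ± 0.37) and dehydrin RAB 16D (Os11g0453900, 2.09 ± 0.23, control above background on 4 of 6 arrays, 3.59 with the processed signals) led, and a protein phosphatase 2C gene (Os02g0799000) rose 2.64-fold. The set test gave adjusted p = 0.0253, adjusted p = 0.906 with an estimated correlation, and adjusted p = 0.0525 under median centring. Auxin genes fell in 31 of 100 cases and rose in 17 (35 and 21 adjusted over the list alone), and a GH3 homologue (Os05g0500900) rose by 2.17 ± 0.51. Their downward set test gave adjusted p = 0.0389, and adjusted p = 0.906 with an estimated correlation. It was lost with the processed signals (adjusted p = 0.122) and under median centring (adjusted p = 0.364).

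Further lists held calls at 60 min, and none in this paragraph passed the set test, although the AP2/ERF list (adjusted p = 0.0827) did with the processed signals (adjusted p = 0.0435). Over all tested genes 29.1% were called at 60 min, so a count near or below that share is not read as a response of its list. DNA repair genes rose in 9 of 25 cases and fell in 3 (9 and 5 adjusted over the list alone). The photolyase genes Os06g0661800 (1.87 ± 0.11), Os02g0204400 (1.21 ± 0.12) and Os10g0167600 (0.67 ± 0.11) again led. Light signalling genes rose in 9 and fell in 11 of 42 cases (9 and 14 adjusted over the list alone), with Os11g0118300 (1.27 ± 0.15) and HY5 (Os01g0174000, 0.97 ± 0.19) upward. Of 137 MYB genes 39 rose and 18 fell (41 and 23 adjusted over the list alone), with Os06g0205100 at 3.04 ± 0.27. NAC genes rose in 13 of 45 cases and fell in 3 (15 and 5 adjusted over the list alone), with Os05g0194500 at 1.23 ± 0.04. AP2/ERF genes rose in 12 of 31 cases and fell in 2 (18 and 4 adjusted over the list alone), with Os03g0120900 at 0.90 ± 0.09. Of the 13 ethylene responsive element binding factors that its pattern missed 6 rose and 3 fell. Chosen after their values were seen, Os05g0497300 rose by 1.23 ± 0.33 and Os05g0497200 by 1.15 ± 0.05. C2H2 zinc finger genes rose in 13 and fell in 12 of 68 cases (14 and 13 adjusted over the list alone). Gibberellin genes rose in 9 and fell in 6 of 34 cases (10 and 6 adjusted over the list alone). Gibberellin 2-beta-dioxygenase genes Os01g0757200 (1.29 ± 0.09) and Os01g0209700 (1.12 ± 0.32, control above background on 5 of 6 arrays, 1.88 with the processed signals), whose enzyme inactivates gibberellin, rose. Ethylene synthesis genes rose in 3 and fell in 3 of 14 cases (3 and 3 adjusted over the list alone). An ACC oxidase gene (Os05g0149400) rose by 1.86 ± 0.43. The ACC synthase gene Os04g0578000, not well above background in the control on any of 6 arrays, was called upward (adjusted p = 0.000985). Its ratio was -0.075 and not called under median centring, and 2.26 with the processed signals, so no fold or bound is given. Cell wall genes rose in 32 and fell in 10 of 134 cases (32 and 10 adjusted over the list alone), with alpha-expansin OsEXPA5 (Os02g0744200) at 1.24 ± 0.03. Redox genes rose in 75 and fell in 25 of 355 cases (75 and 25 adjusted over the list alone), with a glutathione S-transferase gene (Os01g0558100) at 1.89 ± 0.24. Calcium signalling genes rose in 33 and fell in 30 of 151 cases (34 and 32 adjusted over the list alone). MAP kinase genes rose in 8 and fell in 5 of 32 cases (9 and 5 adjusted over the list alone), with a blast and wounding induced kinase gene (Os05g0566400) at 1.43 ± 0.27. Pathogenesis-related genes rose in 29 and fell in 14 of 124 cases (32 and 17 adjusted over the list alone). Its largest called members were the ERF domain factor genes Os01g0868000 (1.66 ± 0.22) and Os02g0764700 (1.55 ± 0.51, control above background on 3 of 6 arrays, 2.70 with the processed signals) and a Bowman-Birk proteinase inhibitor gene (Os01g0123900, 1.62 ± 0.38). ERF domain factors, which are regulators and not defence proteins, made up 31 of the 124 genes and held 15 of the rises and 6 of the falls, and the other 93 genes held 14 and 8. Heat shock and chaperone genes rose in 27 and fell in 18 of 176 cases (27 and 18 adjusted over the list alone), with heat shock transcription factor 31 (Os01g0571300) at 1.53 ± 0.11. Diterpenoid phytoalexin genes rose in 2 and fell in 1 of 8 cases (2 and 1 adjusted over the list alone). Under median centring the direction of the set test turned at 60 min for the light signalling, heat shock, NAC, ethylene, calcium, MAP kinase, pathogenesis-related and diterpenoid lists, and for the ethylene list also with the processed signals. The median and the mean log2 ratio at 60 min differed in sign for the ethylene, calcium, MAP kinase, tetrapyrrole and cytokinin lists, and for the heat shock and C2H2 lists both were above 0 while the test pointed downward.

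Housekeeping groups and markers of other tissue were also measured at 60 min. Ribosomal protein genes rose in 29 of 299 cases and fell in 0, with 0 adjusted over the list alone, and had a median of 0.09. Their set test gave adjusted p = 0.0460, and adjusted p = 0.922 with an estimated correlation. Proteasome genes fell in 8 of 54 cases and rose in 0, with 0 adjusted over the list alone, and had a median of -0.06. Their set test gave adjusted p = 0.0109, and adjusted p = 0.906 with an estimated correlation, and the list shifted upward under median centring (adjusted p = 4.41e-05). The ubiquitin ligase list matched 5 genes with a median of 0.25, of which 3 rose and 0 fell (4 and 0 adjusted over the list alone), and its pattern missed 217 genes described as Zn-finger RING, of which 37 rose and 39 fell. Its set test gave adjusted p = 0.0460, adjusted p = 0.673 with an estimated correlation, adjusted p = 0.0502 with the occasion as a block and adjusted p = 0.317 under median centring. Histone genes rose in 7 and fell in 2 of 46 cases (7 and 2 adjusted over the list alone), and passed the set test upward under median centring (adjusted p = 1.58e-06). Photosynthesis genes rose in 16 and fell in 6 of 92 cases (14 and 5 adjusted over the list alone), and tetrapyrrole genes rose in 2 of 12 (2 adjusted over the list alone). Cytoskeleton genes rose in 11 and fell in 7 of 68 cases (10 and 6 adjusted over the list alone), and passed upward under median centring (adjusted p = 0.0307). Seed storage and endosperm genes, markers of grain tissue next to the coleoptile, rose in 4 and fell in 1 of 17 cases (4 and 1 adjusted over the list alone). Their median was 0.07, and their set test turned downward under median centring without passing (adjusted p = 0.105). The circadian list matched 4 genes, with 0 calls at either time and 0 adjusted over the list alone. The cytokinin list matched 3 genes. A type-A response regulator gene (Os11g0143300) fell by 0.35 ± 0.14 at 20 min, and a cytokinin-regulated kinase gene (Os05g0127300) rose by 0.47 ± 0.08 at 60 min, each with 1 call adjusted over the list alone. The circadian and cytokinin lists were too small for the set test. Of the 84 genes named through a list at 60 min, 63 passed without each occasion in turn, and 7 were not called with the processed signals.

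**Figure D2:**
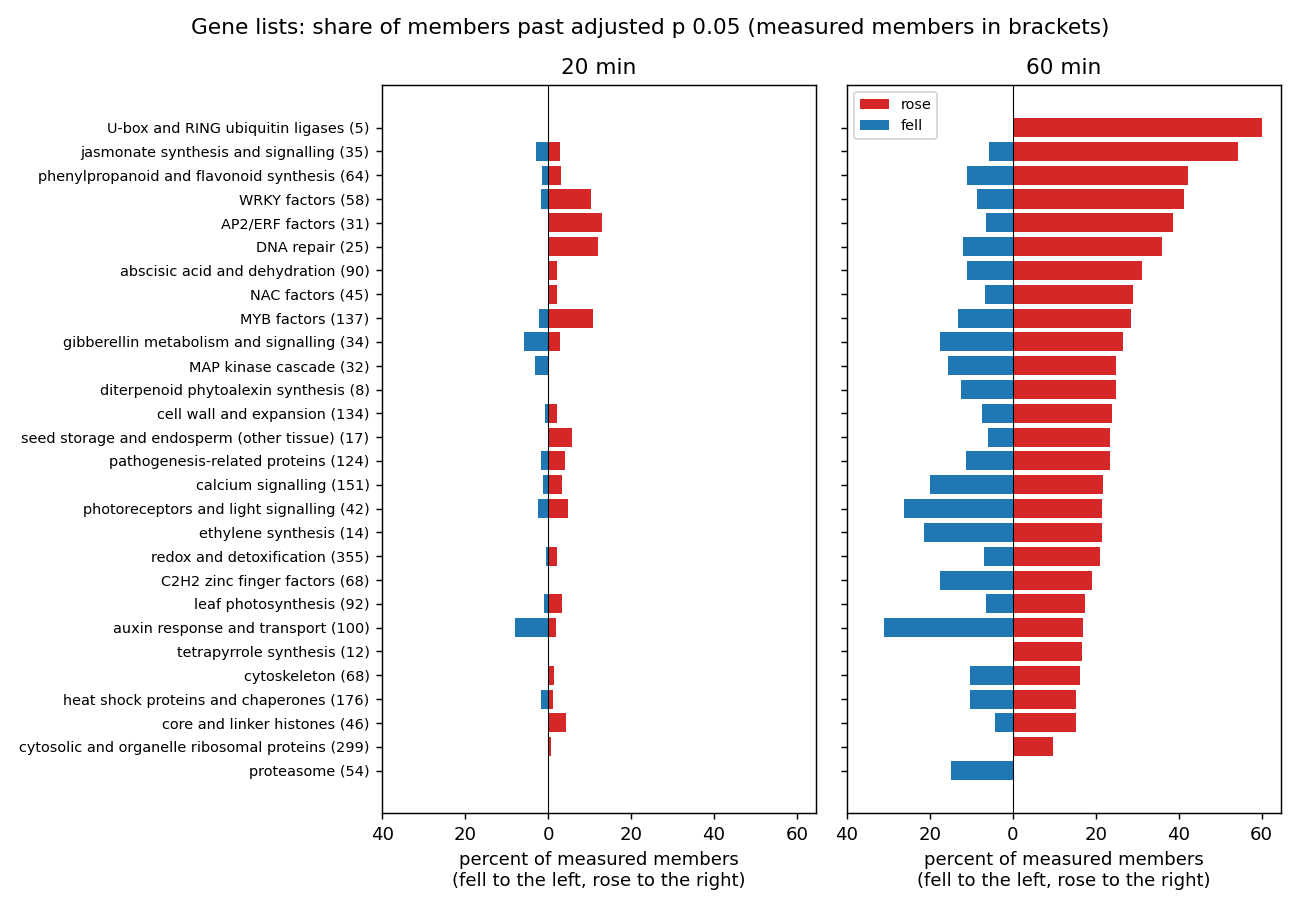
Percent of measured members (horizontal axis) that rose (red, right) or fell (blue, left) at an adjusted p under 0.05, per gene list, at 20 min (left panel) and 60 min (right panel), with the number of measured members in brackets. At 60 min 19 of 35 jasmonate genes and 27 of 64 phenylpropanoid genes rose. Over all tested genes 4.0% were called at 20 min and 29.1% at 60 min.

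Among called genes with a usable description, chalcone synthase (Os07g0526400) had the largest difference between 60 and 20 min, in which a constant dye effect cancels. It was higher at 60 min by 4.22 ± 0.83 (adjusted p = 0.00134), while the difference of the bHLH gene Os04g0301500 was 4.89 and not called (adjusted p = 0.0732). A cytochrome P450 gene (Os12g0582700, 3.18 ± 0.44), the isopenicillin N synthase family gene Os04g0522500 (3.13 ± 0.32) and the phenylalanine ammonia-lyase genes Os04g0518400 (3.04 ± 0.25) and Os05g0427400 (2.93 ± 0.29) came next. An esterase/lipase domain gene (Os07g0526600, 2.89 ± 0.58), a gene described as an obtusifoliol demethylase (Os05g0211100, 2.81 ± 0.41) and the thioesterase gene Os01g0882100 (2.68 ± 0.05) completed the named genes that were higher. With the processed signals Os12g0582700 and Os07g0526600 were not called. The differences of chalcone synthase, Os05g0211100 and Os07g0526600 were 5.37, 5.15 and 5.06 there, so their size and rank depended on the signal used. For Os05g0211100 and Os07g0526600 the control was above background on 2 of 6 arrays at 60 min. Genes lower at 60 than at 20 min included bHLH genes Os03g0188400 (-1.36 ± 0.29) and Os02g0705500 (-1.08 ± 0.34), a glutathione S-transferase gene (Os10g0525500, -1.14 ± 0.29) and a dynein light chain gene (Os01g0555600, -1.05 ± 0.23). The VQ domain gene Os06g0618700 (-1.11 ± 0.19) and the ERF gene Os03g0183300 (-1.07 ± 0.20) were lower too. A RING domain gene (Os10g0544600, -1.03 ± 0.60) was not called with the occasion as a block, and its 4 probes had ratios of -0.56 to 0.22 at 60 min. The AP2 gene Os01g0141000, which rose at 20 min, was 2.15-fold lower at 60 min (adjusted p = 0.0490), a call lost without background correction, with the processed signals and with either control alone. The limma test called 1574 genes, of which 1215 were higher at 60 min and 359 lower, and 2156 genes with the occasion as a block. Without occasion 1, 2 or 3 the test called 552, 529 and 566 genes, and against control 2 alone 929, and 8 of the 16 named genes passed without each occasion in turn. The call was lost without occasion 2 for Os05g0427400 (2.92) and without occasion 1 or 2 for Os12g0582700 (3.36 and 3.25), and without 1 or 2 of the occasions, at ratios of -1.46 to -0.77, for Os03g0188400, Os02g0705500, Os10g0525500, Os06g0618700, Os01g0141000 and Os10g0544600. The times always lay at different positions on the slides, so position and time cannot be told apart.

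Phenylpropanoid genes were higher at 60 than at 20 min in 20 of 64 cases and lower in 1 (26 and 1 adjusted over the list alone). Their set test gave adjusted p = 4.58e-07, and adjusted p = 0.673 with an estimated correlation. Jasmonate genes were higher in 14 of 35 cases and lower in 0 (17 and 0 adjusted over the list alone, set test adjusted p = 1.05e-07, adjusted p = 0.673 with an estimated correlation). Enzymes of jasmonate synthesis were among them, with allene oxide synthase (Os03g0767000) at 1.57 ± 0.27 and lipoxygenase 1 (Os03g0700400) at 1.56 ± 0.12. The potassium channel gene Os07g0108800 in this list was called upward at 20 min (0.24 ± 0.05), with the opposite sign under median centring. Abscisic acid genes were higher in 11 and lower in 2 of 90 cases (18 and 4 adjusted over the list alone). Their set test gave adjusted p = 0.00235, and adjusted p = 0.906 with an estimated correlation. Cell wall genes were higher in 13 and lower in 0 of 134 cases (16 and 1 adjusted over the list alone). They were led by a pectinesterase inhibitor gene (Os05g0149000, 1.26 ± 0.25), OsEXPA5 (Os02g0744200, 1.09 ± 0.14) and cellulose synthase-8 (Os07g0252400, 0.98 ± 0.12). The set test of the cell wall list gave adjusted p = 0.0460, adjusted p = 0.722 with an estimated correlation and adjusted p = 0.0502 with the occasion as a block. WRKY genes were higher in 7 and lower in 1 of 58 cases (11 and 2 adjusted over the list alone), with a set test adjusted p = 0.0842, adjusted p = 0.0261 with the occasion as a block and adjusted p = 0.906 with an estimated correlation. The ubiquitin ligase list was higher in 1 of 5 cases (4 adjusted over the list alone, set test adjusted p = 0.00704, adjusted p = 0.673 with an estimated correlation). Light signalling genes were higher in 2 and lower in 2 of 42 cases (3 and 3 adjusted over the list alone, set test downward at adjusted p = 0.537). The COP1 gene (Os02g0771100), a repressor of light responses, was higher by 0.59 ± 0.09, and phytochrome-interacting factor 3 (Os12g0610200, adjusted p = 0.00451) and the NPH3 gene Os12g0583500 (-0.57 ± 0.05) were lower. The call was lost without occasion 3 for each of these 3 genes, and without occasion 2 for Os02g0771100 and Os12g0583500. Of the 63 genes named through a list for this difference, 29 passed without each occasion in turn.

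Overlap between the times was compared with chance. Among 24162 genes 577 rose and 262 fell at both times, against 110.5 and 39.6 for independent lists of those sizes, and 11 genes were called in opposite directions. Independent lists leave out the shared controls, which add to the overlap with no effect at all. Across genes, which are not independent replicates, the 20 and 60 min ratios correlated with r = 0.638 and a covariance of 0.0360. Simulated unchanged samples against the same controls gave r = 0.298 and a covariance of 0.00230, a difference in covariance of 0.0337. A constant dye effect of the probes, which neither reference includes, would also raise the overlap, r and covariance, so no excess is read as a shared effect. With separate controls r was 0.583 (20 min against control 1, 60 min against control 2) and 0.527 (the reverse). Of the 655 genes that rose at 20 min, 405 had a higher ratio at 60 min. Of the 50 that rose at least 2-fold at 20 min, 46 also rose at 60 min.

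**Figure D3:**
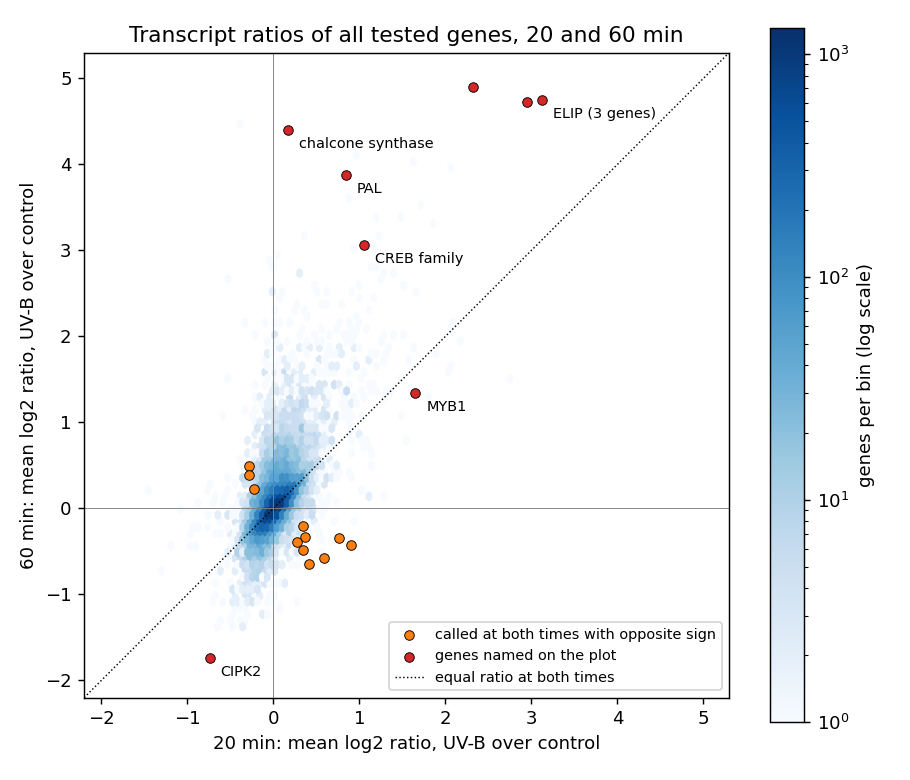
Mean log2 ratio of UV-B over control at 20 min (horizontal axis) and 60 min (vertical axis) for 24162 genes, shaded by the number of genes per bin on a log scale, with named genes in red, the 11 genes called in opposite directions in orange and a dotted line of equal ratios. Chalcone synthase (Os07g0526400) lies at 0.17 at 20 min and 4.40 at 60 min.

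Untreated coleoptiles taken before and after the irradiation gave the background. The limma test called 0 genes between control 2 and control 1 (1452 at an unadjusted p under 0.05, smallest adjusted p = 0.786), and the differences had an SD of 0.11 across genes. Over the 164 genes named by the fixed rule the difference lay between -0.45 and 0.39. It was 0.13, 0.06 and 0.17 for Os07g0178700, Os01g0246400 and Os07g0178800, and -0.45 ± 0.10 for chalcone synthase (Os07g0526400), which was not called.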

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

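The test of dye effects for genes without a call between the times was chosen after the result was seen.

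The response differed between the times: the contrast of 60 minus 20 min called 1574 genes, among them chalcone synthase (Os07g0526400). Of the 10 splits of the 6 averaged ratios into 3 and 3, only the real grouping gave as many. The highest of the others gave 21, and the splits are too few for a share under 0.05. Among the 4 splits that part all pairs of an occasion, the highest other gave 0. Turning the sign of occasions gave 4 splits per comparison, also too few. At 20 min the real signs gave 978 genes and the highest other split 0. At 60 min the real signs gave 7042 and the highest other 0, and for the controls all 4 gave 0.

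The breadth of the 60 min response could come from a constant dye preference of the probes, since UV-B RNA was always in Cy5, and such a preference predicts no difference between the times. Genes were called and signed from 2 occasions, and the difference of 60 minus 20 min was read in the occasion left out. It had the sign of the 60 min call in 93.1%, 87.8% and 88.1% of the 3182, 3753 and 3595 genes called without occasion 1, 2 or 3. This argues against a dye preference as the whole cause for these sets. Genes called at 60 min only with all 3 occasions were not tested. For each of the 5507 genes called at 60 min without a call between the times, taken singly, dye and UV-B cannot be told apart, because there was no dye swap. A missing call between the times does not show equal ratios, and the share was not computed for these genes alone. UV-B, which the design names, stays open for them, as does elapsed time. Slide position and elapsed time stay open for the difference.

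A set of 11 genes was called at both times with opposite signs. Each passed the test of the difference, which adds no support, because calls in opposite directions in the same fit make it nearly certain. The ERF gene Os03g0183300 went from 0.42 ± 0.13 to -0.65 ± 0.19, the VQ domain gene Os06g0618700 from 0.76 ± 0.27 to -0.35 ± 0.15, and heat stress factor Spl7 (Os04g0568700, chosen after its values were seen) from -0.22 ± 0.03 to 0.22 ± 0.07. Normalization within the arrays could produce such turns, but all 11 kept both signs with the processed signals, without background correction and under median centring, which argues against it. A short-lived response to UV-B, elapsed time, an effect of slide position and false calls at either time all stay open, untested.

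Probes outside the rice loci also carried signal. Of 510 microRNA probes 177 were above background, and at 60 min 31 rose and 55 fell, with a highest ratio of 0.72. At 20 min 43 were called. These probes were fitted apart from the genes, and p was adjusted over the probes above background outside the rice loci only. Their share of calls can thus not be set beside that of the genes.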

How the results depend on the processing

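The setting without the 60 min array of occasion 2 against control 2, and the replicate block in the set test, were chosen after seeing the data, and the cause was not tested except where stated. The genes changed at 20 min numbered 978. They numbered 242 with Agilent's processed signals and 242 with the authors' series table, which holds the same ratios, 13359 with median centring, 2321 with the replicate block, 4135 with all 12 arrays and occasion as a random block, 455 against control 1 only, 172 against control 2 only, 50 at 2-fold or more, 78 with each time fitted alone, 387 without that array, and 18 to 239 without 1 replicate. The genes changed at 60 min numbered 7042, and 15768 with median centring, 503 at 2-fold or more, and 3182 to 3753 without 1 replicate. The genes changed between 20 and 60 min numbered 1574, and 4595 with the random block, 929 against control 2 only, 245 at 2-fold or more, and 529 to 566 without 1 replicate. Fewer samples were fitted without 1 replicate. The random block entered both arrays of a treated sample as separate values, although such arrays correlated at 0.68 to 0.90. Against 0 the replicate block leaves the spread between occasions out of the test. The counts of the random block, and those of the replicate block against 0, can thus be too high. Median centring gave 1841 genes between the times, where a constant dye effect cancels, against 15768 at 60 min. Its calls and list shifts against 0 can thus hold dye differences that vary with intensity. The replicate block gave 8872 genes at 60 min and 2156 between the times. The other settings left these counts within 1.5 times, and the controls differed in 0 genes under each setting run. The correlation of the times, 0.638, was 0.793 with median centring and 0.527 for 20 min against control 2 with 60 min against control 1. The set test called 18 shifts, 0 with an estimated correlation, 19 with median centring (11 shared), 18 with processed signals (16 shared) and 16 with the replicate block (15 shared), which changed no list call besides those given with its value. Named values were run under other background correction and scaling, an intensity trend in the variance, both blocks, single controls and without each occasion. They were not run under the probe filters, kept outliers, all probes, 2-fold, single-time fits or without that array. Of 241 named values 104 passed under every setting run for them, 2 were lost with the replicate block and 66 with the processed signals. Under median centring 11 changed sign: at 20 min Os04g0529100 (-0.20), Os07g0108800 (-0.32) and Os12g0454600 (0.034), and at 60 min Os04g0578000 (-0.075), Os05g0149300 (-0.086), Os06g0568600 (-0.17), Os01g0178700 (-0.058), Os06g0192600 (0.21), Os09g0505600 (0.13), Os07g0691800 (0.21) and Os08g0473900 (-0.14). Signal over background limits the ratios of probes whose control channel was dim, such as that of Os04g0578000.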

Other observations

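The tests of gene families and of neighbouring loci, and the genes named here, were chosen after the results were seen. Genes with the same array description were tested for an excess of changes of at least 2-fold at 60 min, over 520 descriptions with at least 5 genes and a background of 24162 genes (1040 tests). ZIM domain genes passed, with 6 of 12 rising at least 2-fold (adjusted p = 4.02e-05, hypergeometric test), a theme that overlaps the jasmonate list, whose call was lost with an estimated correlation (adjusted p = 0.673). The hypergeometric test treats genes as independent, which genes regulated together are not, so its p values can be too small. Of the 6 ZIM domain genes, Os03g0180900 and Os03g0181100 were not called at 60 min without occasion 1 or without occasion 2. Os09g0439200 rose by 1.09 ± 0.07 at 60 min and had a ratio of -0.01 ± 0.05 at 20 min. SAUR genes, early auxin-response genes, passed in the other direction, with 3 of 17 falling at least 2-fold (adjusted p = 0.00182), among them Os08g0118500 (-1.07 ± 0.26). The others, Os09g0546000 and Os09g0546300, lie close in locus order, so cross-hybridization stays open for them. A further SAUR gene, Os02g0643800, rose by 1.02 ± 0.15.

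Genes that rose at least 2-fold at 60 min were often neighbours in locus order. Of 24150 neighbouring pairs 33 had both members among the 460 genes, against a mean of 8.73 and a highest value of 21 in 10000 shuffles. Chalcone synthase (Os07g0526400) and the esterase/lipase gene Os07g0526600 formed such a pair. Cross-hybridization of tandem copies could produce such pairs. After 9 pairs with the same description and 5 whose probes share a run of 15 bases were left out, 19 pairs remained, below the highest shuffle of 21 that was set as the bound. Although 8 of 10000 shuffles reached 19, the test does not decide, and pairs of related genes remained, such as the oxo-phytodienoic acid reductase genes Os06g0216200 and Os06g0216300. No biological explanation was tested.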
